A study of Homo sapiens with 4 samples.

How the data were processed

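Open chromatin was measured by ATAC-seq, in which a transposase cuts accessible DNA and inserts sequencing adapters, in 4 libraries of snap-frozen human kidney cortex. Per the labels, nuclei were sorted for 1 library and not sorted for another, and for the other 2 libraries the labels did not give the sorting. The last 2 are called sorting not given 1 and 2, numbers that only name them. The labels' protocols describe a homogenised preparation without sorting and a later one in which nuclei were lysed in another buffer and sorted to remove debris, so sorting and lysis may have differed together. The titles of the sorted and unsorted libraries begin alike, so the pair may share tissue, but the labels do not say whether any libraries came from the same person, and no detail of a person is given here.

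The authors called peaks separately in each library, per the names of the peaks in the deposited lists. The submitters' processing notes name cutadapt 2.10, Bowtie2 2.4.1, Picard 2.26.10, MACS2 2.1.2 and build hg38. The role of each tool, its options, any shift of reads for the transposase and the calling threshold are not given in the sources used here. Each deposited peak carries a fold enrichment over the caller's background at its summit, a ratio, and the -log10 of a p-value and of a q-value. The deposited score is the -log10 q multiplied by 10 and cut to a whole number and was not used. These are the authors' values for single peaks, and they served here only to describe, rank or filter peaks within a list. Where -log10 q values of several libraries stand side by side, they also reflect depth and do not compare peak strength.

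Peaks on the 22 autosomes were used. Sex chromosomes were left out because the tissue came from people. Genes of the HLA region (hg38 chromosome 6, positions 28000000 to 34000000) and 12 genes with common whole-gene deletions were not named, since a missing peak there could be a donor's variant. Peaks were shared when they overlapped by 1 base or more. The 50000 peaks with the highest -log10 q of each library were used where lists of equal length were needed, and are called the strongest peaks.

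Genes were the 19126 autosomal protein-coding genes of a RefSeq table of assembly GRCh38.p14, which has the same coordinates as hg38. The table held gene starts and ends but no strand and no transcripts, so the planned promoter window became a window of 1000 bases around either annotated end of a gene, called a gene end. Exons, introns and untranslated regions were not used, and start sites inside a gene were not counted. SLC4A4, CDKN1A and DNAJB1 therefore had no gene-end peak in any library while 4475, 1142 and 4391 bases of them lay under the strongest peaks of the sorted library (genes chosen after their values were seen). No genome sequence was used, so the planned count of transcription factor motifs was not run.

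Peak coverage of a gene was the number of its bases, with 2000 bases on both sides, under the strongest peaks. The plan had 2000 bases upstream only, which could not be used without the strand. There were 20 lists of marker genes, holding 424 genes, fixed before the data were examined. A list's mean coverage was placed among 10000 random lists of the same size matched on gene length in 20 bins. The sorted minus unsorted difference was placed among random lists matched on length and on the mean of both libraries in 10 bins each. A list was called high above the 97.5th percentile and low below the 2.5th. Such percentiles describe these libraries only. With 1 sorted and 1 unsorted library, no test between groups was possible, and differences have no replicate check. The difference between the 2 libraries with sorting not given was computed in the same way as a yardstick. Shares carry Wilson 95% intervals computed on counts of peaks, merged intervals or genes. They cover counting error only and not variation between libraries.

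Read totals were not used here, but relative depth was recovered. Every peak's fold and p-value with a -log10 p below 290 fitted a whole number of fragments over a Poisson background (100% of such peaks in each library, to within 0.001 in -log10 p and 0.01 in the count). The commonest background gives the genome-wide pileup of each library and with it the relative depth, if all libraries were called with the same settings. On simulated peaks the step recovered 100% of 20000 counts. The sorted minus unsorted comparison was also simulated over 19126 genes. Both simulated libraries were made by thinning the sorted library's coverage base by base, and lists were drawn only from covered genes. There, 8% of unchanged lists fell outside the central 95% and 100% of lists raised 1.5 times lay above it. Real libraries differ by whole peaks, so these shares do not give the error rate or power for the real pair.

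Named genes followed a rule set before the data were examined. In it, gene ends replaced the planned promoter windows, and flanks on both sides replaced the planned upstream flank. For sorted against unsorted, it took the up to 10 genes in each direction with a gene-end peak among the strongest of one library and none at all in the other. For shared peaks, it took the 10 genes of at least 10000 bases with the most bases, flanks included, under merged intervals holding a strong peak of all 4 libraries, relative to gene length. In each list, it took the up to 4 genes with the highest -log10 q in the sorted library, and genes with a gene-end peak in only one of sorted and unsorted. Not every gene that the rule takes is named. Genes named outside it are said to have been chosen after their values were seen. Alternatives set beforehand were -log10 q limits of 2 and 5, 25000, 100000 or all peaks, ranking by fold, a window of 500 bases, an overlap of 50% of a peak, other matching, and leaving out each library. Matching on local gene density (genes within 500000 bases), counting peaks in place of bases, values per HOX cluster, and the overlap of single gene-end peaks were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.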

Results

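The 4 libraries were made from human kidney cortex, the outer kidney, which holds the glomeruli and most of the proximal tubule. The series concerns regulatory effects on blood pressure, in which tubular sodium transport takes part. The sorted library had 168561 autosomal peaks, the unsorted library 176628, and the libraries with sorting not given 191184 and 221788, a mean of 206486 ± 21640 (SD, n = 2). Peaks covered 40.9, 39.3, 42.3 and 49.3 Mb in the same order. The recovered genome-wide background was 2.70 fragments in the sorted and 1.66 in the unsorted library, against 4.36 and 5.23 in the others, so the sorted library was 1.62 times as deep as the unsorted one by this measure. The median peak stood 7.04 and 8.42 times above its local background in the sorted and unsorted libraries, and 4.59 and 4.27 times in the others. The lowest pileup of a called peak was 3.71, 4.81, 2.98 and 2.68 times the genome-wide background in the same order. The medians thus also reflect depth and the calling limit and do not compare signal between libraries.

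The first question was which genes of kidney and of other cells carried open chromatin in each library. Immediate early and stress genes and housekeeping genes were the most densely covered lists in all 4 libraries. Immediate early genes had 1.94 to 2.05 times and housekeeping genes 1.67 to 1.81 times the mean bases of random lists of the same gene lengths, at or above percentile 99.89 in each library. Without matching on gene length both lists lay inside the central range, at 85.8 to 91.0 and 70.4 to 83.5. Ranking by fold also brought the housekeeping list inside it in the sorted library (96.7). Their strongest gene-end peaks in the sorted library lay at HSPA8, JUND, DUSP1 and JUN, and among housekeeping genes at TFRC, POLR2A, SDHA and B2M, a subunit of the class I antigen complex, with a -log10 q of 328. DUSP1 had a -log10 q of 326 in the sorted and 187 in the unsorted library.

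Genes of the proximal tubule, the segment that takes back most filtered solutes, came next among the cell types. A gene-end peak was present at 38 of 39 members in the sorted library (97.4%, interval 86.8% to 99.5%), at 37 in the unsorted library and at 36 in each of the others, against 76.9% to 79.9% of all genes. Their coverage was 1.52 times the random mean in the sorted library, 1.16 in the unsorted, and 1.31 and 1.20 in the others, at percentiles of 99.8, 89.4, 98.7 and 94.1. Members with the strongest gene-end peaks in the sorted library were HPD, GATM, PCK1 and SLC16A9. HPD, an enzyme of tyrosine breakdown (chromosome 12, 121839527 to 121888611), had a -log10 q of 308 in the sorted and 162 in the unsorted library, with folds of 22.6 and 21.4. PCK1, a key enzyme of glucose synthesis (chromosome 20, 57561110 to 57568121), had 197 and 72.2, with folds of 12.7 and 11.7. With peaks ranked by fold, the list lay inside the central range in every library, with percentiles of 75.9, 13.9, 93.8 and 55.0. With 25000 peaks only the sorted library's list was high, at 99.1, against 5.78, 85.1 and 13.4.

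Kidney transcription factor genes had coverage ratios of 1.57 in the sorted, 1.37 in the unsorted and 1.24 and 1.35 in the other libraries, led at gene ends by TFCP2L1, POU3F3, PAX8 and SALL1. Their percentiles were 99.3, 97.545, 91.5 and 97.4, so the list was high in the sorted and unsorted libraries. It was high in every library with 100000 peaks (97.99 to 99.56) and with all peaks (98.69 to 99.63). With peaks ranked by fold, these genes lay inside the central range in every library, at percentiles of 35.9, 43.8, 38.8 and 54.0, as they did with 25000 peaks (45.4 to 96.9). Tubule injury genes had ratios of 1.49, 1.34, 1.11 and 1.11, with the sorted library's at the 98.2nd percentile and the others inside the central range. Their leading gene-end peaks were at CLU, at SOX9, and at a peak shared by KRT8 and KRT18, which encode paired keratins. The list was high in all 4 libraries with 100000 peaks (97.63 to 98.91) and with all peaks (98.1 to 99.7), and in none with 25000 peaks or by fold, where the sorted percentiles were 53.1 and 84.6, or without length matching (sorted 89.4).

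Lists of the distal segments lay on both sides of the random mean. Thick ascending limb genes had ratios of 1.01, 0.858, 0.563 and 0.770, the third of these at the 0.54th percentile, but at 18.2 with 100000 peaks, 38.8 with all and 10.3 without length matching. By fold that library stayed low (1.90), and with 25000 peaks the list was low in all but the sorted library (1.68, 0.02 and 0.72). Distal convoluted and connecting tubule genes had 0.937, 0.886, 0.589 and 0.871, the third of these at the 2.24th percentile, but at 6.45, 3.63 and 8.33 with 25000, 100000 and all peaks and at 17.4 without length matching. By fold it stayed low, at 0.92. Collecting duct principal cell genes had 1.23, 1.16, 1.22 and 1.09, inside the central range. Intercalated cell genes, which include acid-secreting pump subunits, had 0.466 to 0.588 and lay at or below the 2.47th percentile in all 4 libraries, although not when all peaks were used (6.38 to 36.0). With 100000 peaks and without length matching only sorting not given 1 stayed low (1.44 and 0.80), and by fold the unsorted library did not (3.92). Leading gene-end peaks of the thick ascending limb list were at PTGER3, PPP1R1A, KNG1 and TMEM52B, and those of the distal list at CNNM2, WNK1, WNK4 and HSD11B2. Principal cell genes were led by TFCP2L1, HSD11B2 and the sodium channel genes SCNN1G and SCNN1A, and intercalated cell genes by ATP6V1B1, RHBG, ATP6V1C2 and ATP6V0A4. SLC4A1, a chloride and bicarbonate exchanger gene, had a gene-end peak in the sorted (27.1) and none in the unsorted library. Podocyte genes, from the filtering cells of the glomerulus, had ratios of 0.837, 1.09, 0.908 and 1.00, with strong gene-end peaks at CLIC5, ST6GALNAC3 and PODXL.

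Endothelial genes (0.357 to 0.429), stromal and smooth muscle genes (0.445 to 0.517) and leukocyte genes (0.290 to 0.349) were sparsely covered in all 4 libraries, at or below the 0.17th percentile. Lists of tissues that were not sampled lay in a similar range, with 0.280 to 0.323 for hepatocytes, 0.386 to 0.467 for neurons, 0.191 to 0.343 for cardiomyocytes and 0.150 to 0.265 for adrenal cortex. Neuron genes lay at 6.84 and 6.87 in the sorted and unsorted libraries without length matching and at 6.10 and 5.75 with all peaks, and at 3.35 in the sorted library with 100000 peaks. Stromal genes lay at 2.84 in the sorted library without length matching, and cardiomyocyte genes at 2.69 in the unsorted library with all peaks. Adipocyte genes had 0.540 to 0.874. A gene-end peak was present at 22 of 53 leukocyte genes in the sorted library (41.5%, interval 29.3% to 54.9%), 28 in the unsorted, 24 and 37 in the others. For 23 endothelial genes the counts were 10, 14, 15 and 18. PECAM1, KDR, PLVAP, SOX17, ROBO4 and CLDN5 had weak gene-end peaks in the unsorted library and none in the sorted one, with -log10 q from 3.16 at CLDN5 to 8.25 at PECAM1. CDH5 and MMRN2 showed the opposite, at 3.32 and 7.04. Over all genes, 468 had a gene-end peak in the unsorted and none in the sorted library, and 256 the reverse. The endothelial gene-end peaks with the highest -log10 q in the sorted library lay at EHD3, ESAM, LDB2 and SOX7.

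Stromal genes were led in the sorted library by RGS5, COL1A1, ACTA2 and LMOD1, of which RGS5 had a -log10 q of 237 in the sorted and 239 in the unsorted library. Leukocyte genes were led by CD37, SPI1, CD8A and CORO1A. Gene-end peaks present in the unsorted and absent from the sorted library lay at ITGA8 (16.9), LAPTM5, RUNX3, LCK, PRF1, C1QA, TYROBP and S100A9, and the reverse held at NOTCH3 (9.65) and VAV1 (4.00). In the lists of other tissues, leading genes were CYP17A1 and NR5A1 for adrenal cortex, GPD1, PLIN4, LIPE and LPL for adipocytes, and APOA1, FGB, APOC3 and TF for hepatocytes. They were NPPB, ACTC1, TNNT2 and RYR2 for cardiomyocytes and SNAP25, GRIN1, RBFOX3 and SYT1 for neurons. Of these lists, STAR (11.7), CIDEA, FGG, ITIH1, TNNI3, MYL7 and NEUROD6 had a gene-end peak in the unsorted library only of the sorted and unsorted pair, and NR5A1 (6.85) and NKX2-5 (5.25) in the sorted one only. Of the leading peaks named for the lists, those at HPD, GATM, PPP1R1A, WNK4, ATP6V0A4, CLIC5, EHD3, RGS5, CD37, GPD1, TF, B2M, POLR2A and SDHA also lay at the end of a neighbouring gene.

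The list for blood pressure and sodium transport had a gene-end peak at 48 of 55 members in the sorted library, 49 in the unsorted, 47 and 51 in the others, and coverage ratios of 1.14, 1.16, 1.08 and 1.09, all inside the central range, although high without length matching (98.8 to 99.89). Strong gene-end peaks in the sorted library were at CUL3, whose product acts with KLHL3 on WNK kinases, with a -log10 q of 440, at SH2B3 with 321, and at OXSR1 with 280. In the unsorted library these 3 had 269, 150 and 219. AGT, the precursor of angiotensin, had a gene-end peak in the unsorted library, with a -log10 q of 3.81, and none in the sorted one.

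**Figure D1:**
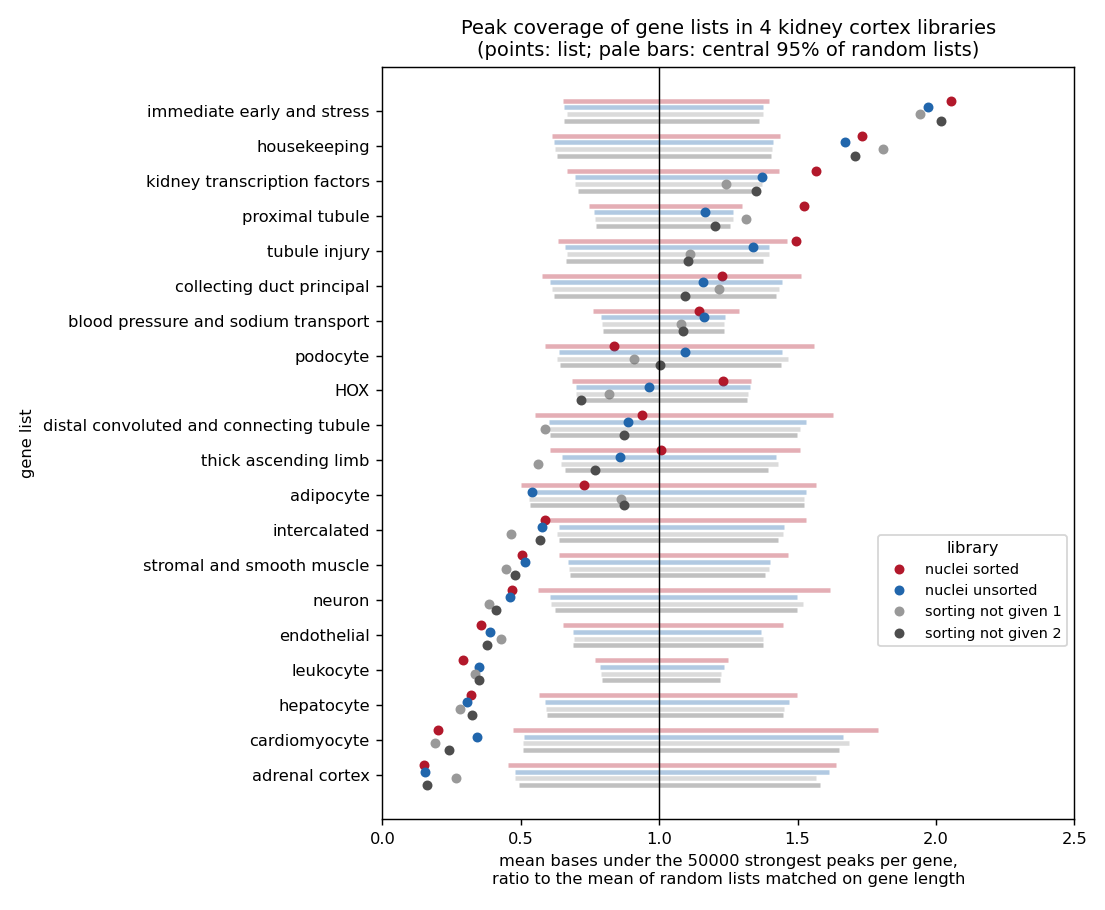
Mean bases under the 50000 strongest peaks per gene of each list (horizontal axis, ratio to the mean of random lists matched on gene length) for 20 gene lists (vertical axis) in the sorted library (red), the unsorted library (blue) and sorting not given 1 and 2 (light and dark grey). Points are list ratios and pale bars the central 95% of 10000 random lists; immediate early genes lie at 1.94 to 2.05 and leukocyte genes at 0.290 to 0.349.

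The second question was how a map from sorted nuclei compares with one from unsorted nuclei. Of the sorted library's peaks, 78.7% (interval 78.5% to 78.9%) overlapped a peak of the unsorted library, and 76.8% (76.6% to 77.0%) of unsorted peaks overlapped a sorted one. Over bases, the Jaccard index was 0.629. Peaks without a partner were weak, with a median -log10 q of 6.29 against 20.6 for partnered peaks in the sorted library, and 5.48 against 16.9 in the unsorted one. Among the 50000 strongest peaks, only 89 sorted and 109 unsorted peaks had no partner of any strength.

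Proximal tubule genes had the largest difference in mean bases between these libraries, while podocyte genes lay further in bases from the mean of their matched random lists. They had a mean of 1499 bases under the strongest peaks in the sorted and 1016 in the unsorted library, a difference of 483 bases where matched random lists gave 198 (central range 76.7 to 324). The difference lay above all 10000 random lists, and 36 of 39 members had more bases in the sorted library, 2 fewer and 1 the same. Over all genes, 10174 had more bases in the sorted library, 4995 fewer and 3957 the same. Strong gene-end peaks were present at 30 members in the sorted and 23 in the unsorted library, with overlapping intervals of 61.7% to 87.4% and 43.4% to 72.9%. These shares were 76.9% and 59.0%, against 64.8% and 66.0% of all genes. SLC5A2, the main glucose carrier of this segment (chromosome 16, 31483123 to 31490769), had a gene-end peak only in the sorted library, at 31482933 to 31483149 with a -log10 q of 17.4. That peak was not among the strongest. The gene's coverage was 1079 bases in the sorted and 955 in the unsorted library, and 1085 and 1303 in the others. Of genes chosen after their values were seen, HNF4A, a regulator of this segment, had 3576 bases in the sorted and 1399 in the unsorted library. In the libraries with sorting not given it had 3256 and 3164, near the sorted value. The phosphate carrier gene SLC34A3 had 992 in the sorted and 264 in the unsorted library, and 348 in each of the others. The libraries with sorting not given differed from each other by 75.5 bases, at the 95.8th percentile, and had 1371 and 1295 bases, between the sorted and unsorted values. For sorted minus the first and minus the second of them, the list lay at percentiles of 97.47 and 100. For unsorted minus each of them it lay at 1.04 and 21.0. The gap between sorted and unsorted thus held low values in the unsorted library as well as high values in the sorted one.

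HOX genes encode developmental regulators ordered in clusters. They had 610 bases in the sorted and 417 in the unsorted library, a difference at percentile 99.93, and 431 and 391 in the others. Neighbouring HOX genes overlap and share peaks, while the random lists drew genes singly. The percentile thus treats 37 genes of 4 clusters as separate members and may overstate how extreme the list is. With all peaks the percentile of the difference was 96.6, and with peaks ranked by fold it was 82.1. All 4 clusters had more bases under strong peaks in the sorted library than in any other. The HOXB cluster (chromosome 17, 48540655 to 48730750) had 5678 bases in the sorted and 3505 in the unsorted library, with 3631 and 4392 in the others. The HOXC cluster (chromosome 12, 53936831 to 54058030) had 3312 and 2016, with 2298 and 1585. Strong gene-end peaks were present at 26 of 37 HOX genes in the sorted library and at 18, 17 and 17 in the others, led in the sorted library by HOXA4, HOXC10, HOXD1 and HOXA5. These shares were 70.3%, 48.6%, 45.9% and 45.9%, against 64.8%, 66.0%, 66.1% and 66.3% of all genes. The sorted share was thus near that of all genes and the others were below it.

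**Figure D2:**
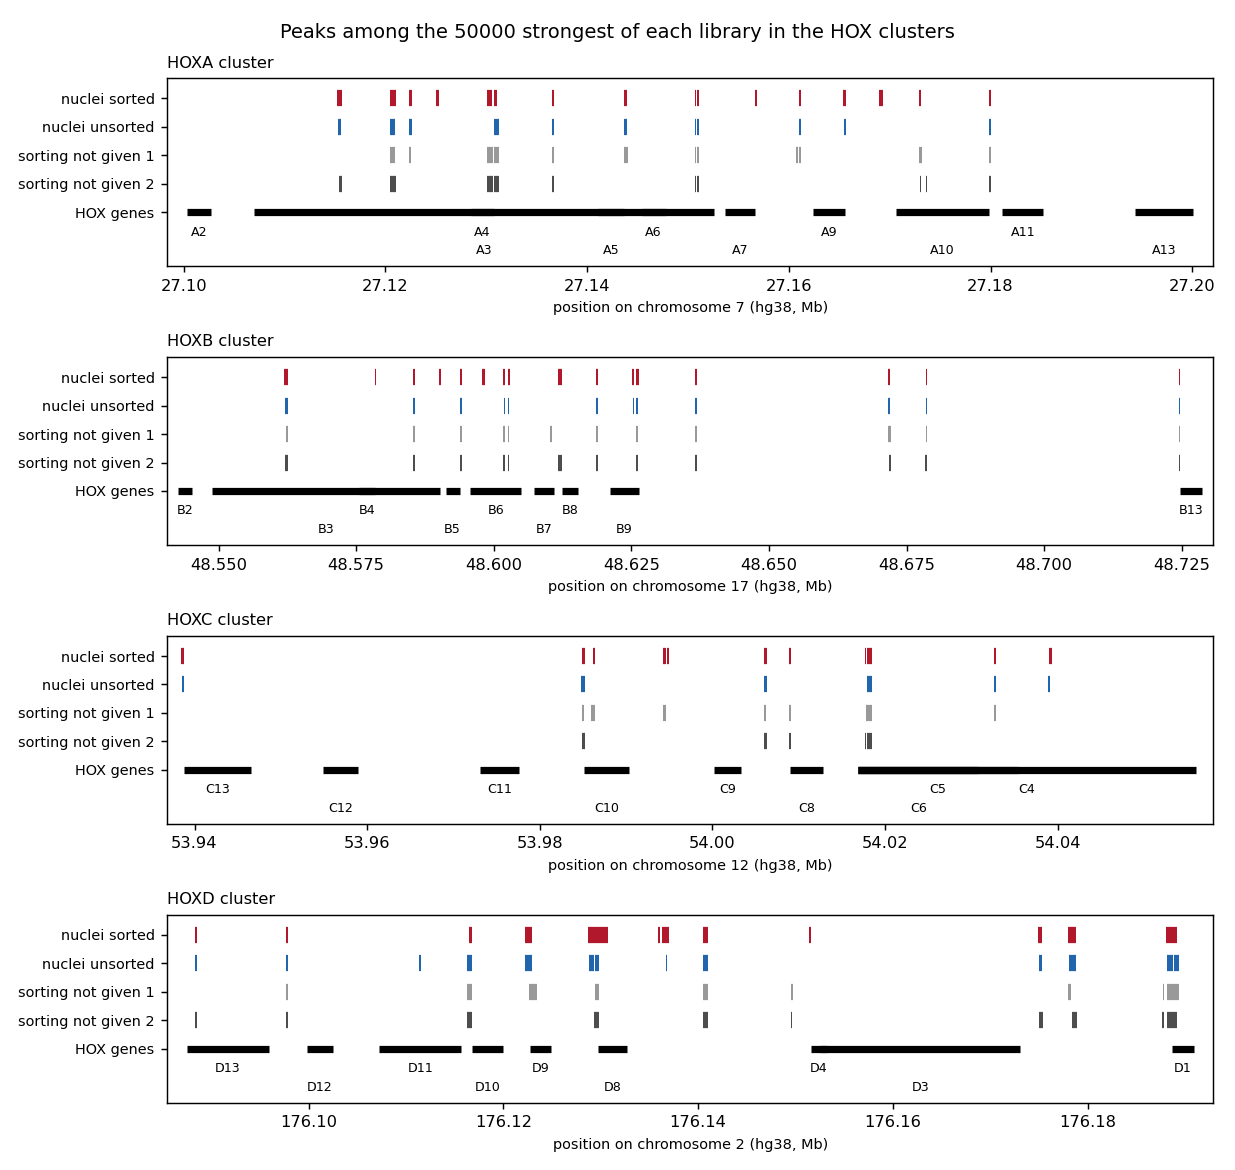
Positions of peaks among the 50000 strongest of each library (coloured marks, one line per library) and of the listed HOX genes (black bars, overlapping genes merge) in the 4 HOX clusters, by position in hg38 (Mb). The sorted library has 16, 16, 11 and 15 peaks in the HOXA, HOXB, HOXC and HOXD clusters, and the unsorted library 11, 12, 6 and 14.

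Podocyte genes went the other way, with 1111 bases in the sorted and 1342 in the unsorted library, a difference of -231 bases at the 0.22nd percentile, where matched random lists gave 150. In the sorted library 7 members had more bases and 7 had fewer, while over all genes 10174 had more and 4995 fewer. The largest gaps among members were at MAGI2 (4177 sorted and 5774 unsorted) and NTNG1 (606 and 1702), chosen after their values were seen. With 25000 peaks the percentile was 5.69. The yardstick pair differed by -203 bases on this list, at the 8.34th percentile. TCF21, a podocyte transcription factor, had a gene-end peak in the unsorted library (-log10 q of 4.495) and none in the sorted one. Adipocyte genes lay at the 99.3rd percentile for the difference, with 480 bases in the sorted and 309 in the unsorted library, but at 21.3 with all peaks and 60.7 with 100000.

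The remaining lists lay inside the central range for the sorted minus unsorted difference. Percentiles were 97.0 for thick ascending limb genes, 88.4 for tubule injury, 84.2 for distal convoluted and connecting tubule, 82.0 for kidney transcription factors, 80.6 for intercalated cells and 69.5 for principal cells. They were 83.6 for neurons, 79.9 for hepatocytes, 72.8 for stromal, 72.1 for immediate early, 60.5 for endothelial, 53.9 for housekeeping and 53.7 for adrenal cortex genes. They were 24.0 for leukocyte, 23.5 for blood pressure and 7.82 for cardiomyocyte genes. The thick ascending limb list was high with 25000 peaks (98.5), with all peaks (99.2), by fold (99.1) and with density matching (98.8). It stayed inside the central range with 100000 peaks (96.9), matched on length only (89.2) and when peaks were counted (46.8). The distal list was high only with all peaks (99.91). These lists also separated the libraries with sorting not given, at percentiles of 0.29 and 0.01 for the first minus the second. Over all genes, the sorted library had 900 bases per gene and the unsorted 801.

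**Figure D3:**
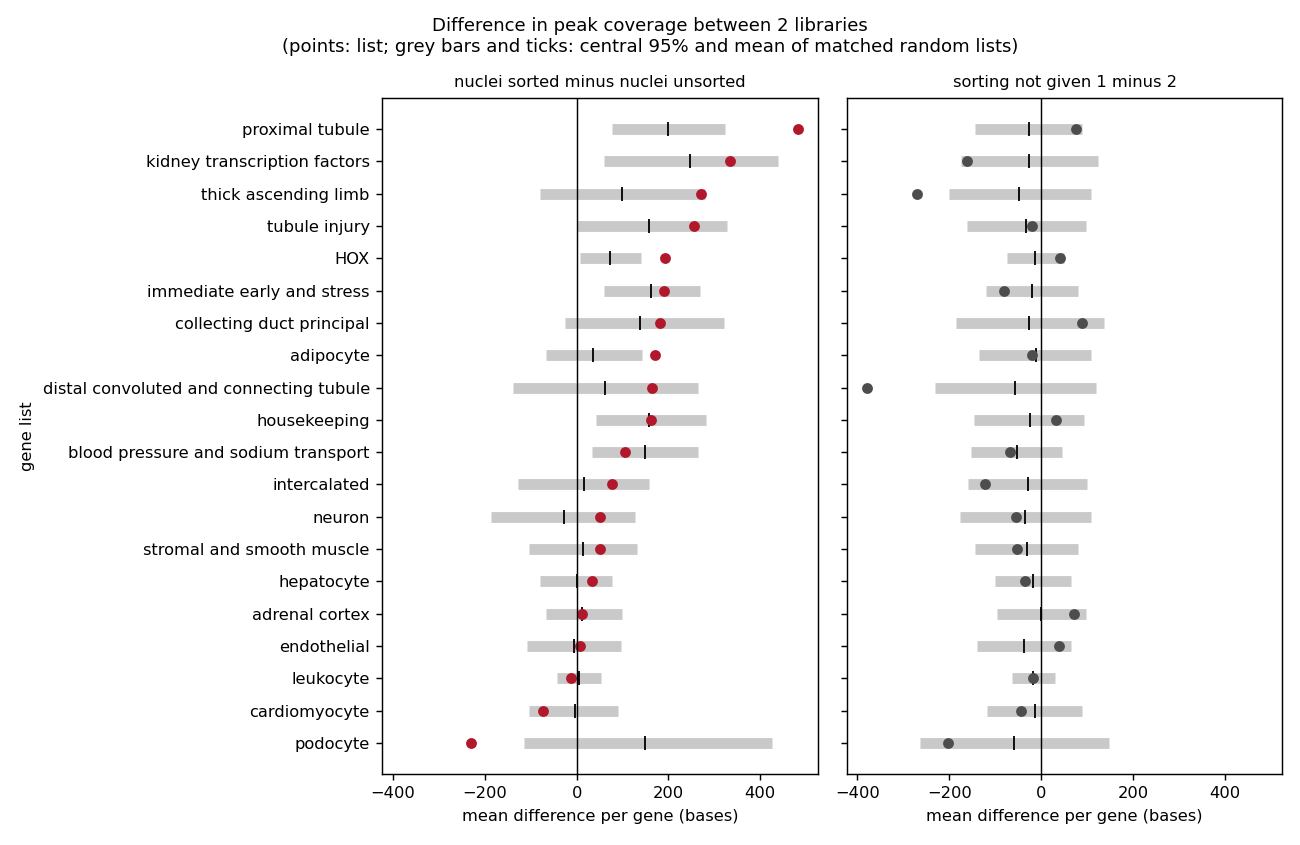
Mean difference per gene in bases under the 50000 strongest peaks (horizontal axis) for 20 gene lists (vertical axis), as sorted minus unsorted (left) and as sorting not given 1 minus 2 (right). Points are lists, grey bars the central 95% and ticks the mean of 10000 matched random lists; the proximal tubule point lies at 483 bases on the left and at 75.5 on the right.

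Very few genes had a strong gene-end peak in one library and none in the other. There were 11 such genes in the sorted library and 7 in the unsorted, and 9 and 13 between the libraries with sorting not given. At 9 of the 11 and 5 of the 7, a peak of the other library overlapped the peak itself but ended outside the window. Such edge cases were SMIM44, LOC124900275, KCNAB3, GRAMD4, LCN15, DDAH1, KIRREL2 and C1orf105 for the sorted library, where the KIRREL2 peak also lay at NPHS1, which encodes nephrin. They were DPYSL4, PCSK1, SLC14A1, a urea transporter gene, CNR1 and ITGB3BP for the unsorted library. Peaks with no partner at all lay at ELANE (chromosome 19, 857087 to 857247, -log10 q of 35.6) and ACSM2B (chromosome 16, 20576258 to 20576417, 30.4) in the sorted library. In the unsorted library they lay at NXPH1 (chromosome 7, 8433998 to 8434191, 48.7) and the chemokine gene CXCL6 (chromosome 4, 73836523 to 73836944, 27.7). NXPH1 and CXCL6 had gene-end peaks in both libraries with sorting not given, with -log10 q of 15.0 and 16.9 at NXPH1 and of 26.4 and 26.2 at CXCL6. ACSM2B had 7.29 and 6.61 there, but the second of these lay at the gene's other end, at 20535224 to 20535364. ELANE, a neutrophil protease gene, had no gene-end peak there.

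The third question was how alike the 4 libraries were. Over the 50000 strongest peaks, the Jaccard index was 0.642 between sorted and unsorted and 0.658 between the libraries with sorting not given. The other 4 pairs had 0.610, 0.612, 0.611 and 0.638, the highest of them between the unsorted library and sorting not given 2. Folder names inside the peak lists differed between the sorted and unsorted libraries and the other 2, and were read here as 2 processing runs. The mean index was 0.6501 within runs and 0.618 across them, a difference of 0.0325. With 100000 or all peaks, not every pair within a run exceeded every pair across runs. Run, preparation and any shared tissue cannot be told apart, because no group appears in both runs, and 6 pairs of 4 libraries allow no test.

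The union of all peaks formed 310861 intervals, of which 92289 (29.7%, interval 29.5% to 29.8%) held a peak of all 4 libraries and 144242 a peak of only 1. Shared intervals lay at gene ends in 19.3% of cases and intervals of a single library in 5.36%. Of each library's 50000 strongest peaks, 97.7% to 98.6% fell in shared intervals. Genes were ranked by bases, flanks included, in merged intervals holding a strong peak of all 4 libraries, relative to gene length. The highest were ESRRA, EML3, PRR7, CRELD1, ATG9A, PCNA, CCDC183, LOC124904106, TRIP10 and CCDC142. They were 10121 to 11851 bases long, near the minimum length set. Flanks counted as bases but not as length, which can favour such genes. ESRRA, which encodes a nuclear receptor of energy metabolism (chromosome 11, 64305524 to 64316743), led with 3165 bases in 4 such intervals. That equals 28.2% of its length. Merged intervals span the peaks of all libraries. Under strong peaks alone, ESRRA had 3045 bases in the sorted and 1553 in the unsorted library, and 2684 and 2427 in the others. PCNA, the sliding clamp of DNA replication, had 2589 bases in such merged intervals, equal to 22.2% of its length. The strongest peaks at ESRRA, EML3, PRR7, CRELD1, ATG9A, PCNA, CCDC183 and CCDC142 also lay at the end of a neighbouring gene.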

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

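Apart from the sex chromosomes, which were left out, the comparisons did not use peaks on sequences outside the assembled chromosomes. The sorted library had 216 such peaks on 43 sequences, the unsorted library 198 on 45, and the libraries with sorting not given 579 on 66 and 512 on 62. They made up 0.109% to 0.292% of each list. With no control library, they were set only against a count of 0, and no biological or technical explanation was tested.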

How the results depend on the processing

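Gene density matching and peak counting were chosen after the result was seen. Peak numbers and their mean kept within 1.5 times of the values given under both stricter limits; leaving out either library with sorting not given moved that mean to 191184 or 221788. Intervals shared by all remaining libraries numbered 97531 to 110466 when 1 library was left out, and 31894 with 50000 peaks each. With a -log10 q of 5, 79.0% of sorted and 80.2% of unsorted peaks were shared and the Jaccard index was 0.644. With 50000 peaks these were 80.1%, 81.3% and 0.642, and with an overlap of 50% the shares were 75.2% and 74.3%. The within-run minus across-run difference was 0.0434 with 25000 peaks, 0.0389 with all and 0.0410 by fold.

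For sorted minus unsorted coverage, 121 of 140 alternative percentiles kept their call, and the proximal tubule list stayed between 99.91 and 100 in all 7. With 25000 peaks, percentiles were 91.1 (adipocyte), 5.69 (podocyte) and 98.5 (thick ascending limb). With 100000 peaks, adipocyte genes had 60.7. With all peaks they had 21.3, HOX 96.6, the distal convoluted list 99.91 and thick ascending limb 99.2. By fold, values were 82.1 (HOX), 77.8 (adipocyte), 0.15 (blood pressure) and 99.1 (thick ascending limb). Matched on length only, they were 87.2 (adipocyte), 99.0 (immediate early), 99.1 (kidney transcription factors) and 0.24 (leukocyte). Gene density matching gave 97.7 (kidney transcription factors) and 98.8 (thick ascending limb), and counting peaks gave 83.8 (adipocyte). The causes were not tested.

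Of 400 alternative coverage percentiles within single libraries, 318 kept their call, 44 lost it and 34 gained it. The other 4, all for HOX genes, also gained a call, on the side of the range opposite to the main value. The main HOX percentiles were 91.3 in the sorted and 41.5 in the unsorted library, and 12.1 and 3.29 in the others. All lay inside the central range. The 4 alternative values were 99.8 for the unsorted library with 100000 peaks and 100 for it with all peaks. They were 99.9 for sorting not given 2 with all peaks and 2.18 for the sorted library by fold. Of 2144 checks of gene-end peaks at named genes, 1958 gave the same presence. Shares of list members with a gene-end peak moved in 61 of 320 cases, and shares of peaks at gene ends in 8 of 12. Motif counts and a window of 2000 bases upstream and 500 downstream were not run. No paired analysis was possible because the sorted and unsorted groups hold 1 library each. The unsorted library had the lowest depth, so weak peaks absent from it are not shown to be absent from the tissue.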

Other observations

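The ranking by fold, the use of all peaks and, for proximal tubule genes, the 25000 strongest peaks were set beforehand. Tests chosen only after the result was seen were peak counting, gene density, strong unpartnered peaks, the share of proximal tubule nuclei and HOX clusters. For HOX genes, the use of the planned 25000 strongest peaks to weigh depth was also chosen then.

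The few strong peaks without any partner differed in place between the sorted and unsorted libraries. The 89 sorted peaks absent from the unsorted library had a median of 15 protein-coding genes within 500000 bases, against 9 for all strong sorted peaks, and 21 of them (23.6%) lay at gene ends, against 29.9% of all strong sorted peaks. The 109 unsorted peaks absent from the sorted library had a median of 3 such genes, 79 (72.5%, interval 63.4% to 80.0%) lay outside genes, against 32.0% of all strong unsorted peaks, and 5 at gene ends. Of these 109, 106 overlapped a peak of sorting not given 2 and 81 a peak of sorting not given 1. Of the 89, 68 overlapped a peak of sorting not given 1, 68 a peak of sorting not given 2, and 56 a peak of both. Between the libraries with sorting not given, the first had 205 and the second 616 such peaks, with medians of 8 and 6 genes near. Of these, 6.34% and 6.49% lay at gene ends and 48.3% and 42.5% outside genes.

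The same order appeared over all genes. In the 3826 genes with the fewest neighbours (median of 3), sorted and unsorted coverage were 1097 and 1095 bases. In the 3825 genes with the most (median of 35), they were 740 and 606 bases, a difference of 134. The libraries with sorting not given differed by -67.0 and -22.0 bases in these sets. GC content was not analysed here.

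Proximal tubule genes had more coverage in the sorted than in the unsorted library. Wider peaks in the deeper sorted library would have brought the list into the central range when peaks were counted in place of bases, but its percentile was 99.99. Weak peaks missed in the shallower library were predicted to do so among the 25000 strongest peaks, where the percentile was 100. The main comparison already left out peaks near the calling limit, so that check could not decide on depth. A preference for gene-dense regions would have brought the list into the central range under density matching, where its percentile was 99.97. A larger share of proximal tubule nuclei in the sorted library may account for the difference and stays open. Of the 4 lists for podocyte, endothelial, stromal and leukocyte genes, 2 and not all 4 lay below the 50th percentile. Sorting, lysis and library-to-library variation cannot be told apart with 1 library each.

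HOX genes had more coverage in the sorted library than in each of the others. A single cluster counted for each of its genes would not give more bases in all 4 clusters, as was seen. Within clusters, overlapping genes still shared peaks while random lists drew genes singly, so the HOX percentiles may overstate how extreme the list is. Weak peaks missed in the shallower library were predicted to bring the sorted minus unsorted difference into the central range among the 25000 strongest peaks. Its percentile there was 100. The main comparison already left out peaks near the calling limit, so this check could not decide on depth. Under density matching the difference stayed at the 99.8th percentile. The call was lost when peaks were ranked by fold (82.1) and with all peaks (96.6), so it may depend on how peaks are chosen, and whether the nuclei differed was not tested.

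No deposited list held a mitochondrial peak, with 0 in each of the 4 libraries. Whether such reads or peaks were removed before deposit was not examined, so the count does not measure mitochondrial DNA.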
